A study of Caenorhabditis elegans with 2 samples.

How the data were processed

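Tagged ALY-2 was immunoprecipitated from whole L4 larvae of strain OP217, and chromatin was fragmented by sonication, per the labels. The samples are labelled biological replicates 1 and 2 of 1 line, and nothing in the labels says whether they came from separate cultures or days, so the spread between them may be partly technical. There is 1 group, and no control sample values are used here.

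The authors' 8 deposited peak lists cover 2 builds, ce10 and ce11, per the labels and the accompanying descriptions of each file. In each build there is a permissive list per replicate, a permissive list from the pooled alignments of both replicates, and the list past the optimal threshold of the irreproducible discovery rate (IDR), a measure of how reproducible a peak's rank is. The permissive lists hold peaks and background as input for IDR, per the same descriptions, and were derived with a control alignment. The signal column of each list is the authors' deposited signal value for a peak. Its scale is not stated, so it was used to rank and describe peaks within a list, and between lists only for correlations across peaks and for rank-matched ce10 and ce11 values. The deposited -log10 column holds the −log10 of the q-value, and the p column is unset. The peak caller, aligner, their versions and the IDR threshold are not given in the sources used here. Depth per replicate is unknown, so intervals cover counting error over peaks only. All columns used were matched to a sample or to the pooled replicates.

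The ce11 lists were set against the Ensembl release 115 annotation of the same assembly, and all peaks lay within its chromosome lengths. The ce10 lists were used only for counts, signal and overlap within ce10, and no coordinate was converted. Summits were classed in order as promoter (1000 bp upstream to 200 bp downstream of a transcript start), 5' UTR, coding exon, noncoding RNA exon, 3' UTR, intron, within 500 bp downstream of a transcript end, or other intergenic, and compared with 10000 random placements within chromosomes (two-sided permutation p, Benjamini-Hochberg adjusted). Promoters include those of noncoding RNA genes, which are short and many. A gene was a target if a summit lay in the same promoter window of any of its transcripts. Gene lists were fixed before the data were examined, and were tested against all annotated nuclear genes by two-sided Fisher's exact test with adjustment over 24 lists. Genes that share a peak are not independent, so the number of peaks is given beside the number of genes. Chromosome counts were tested by exact binomial tests and by 100000 multinomial draws.

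Replicate sharing was the overlap by at least 1 bp of the 193 strongest peaks by signal, against 1000 shuffles within chromosomes, and correlations across peaks used 100000 permutations. GC content was taken over 100 bp on each side of the summit. Sequences of 6 bases were compared between 50 bp on each side of the summit and a flank 500 to 600 bp away by the exact McNemar test. The adjusted p threshold was 0.05, and intervals are exact (Clopper-Pearson) at 95%. Named genes were the nearest-start genes of the 25 strongest peaks, the members of a list with a target call, and aly-1, aly-2, aly-3 and unc-119. Of the 16 tRNA genes, 3 are named as examples to keep the text short. The genes prg-1, hsp-3, alg-1, hrde-1, unc-54, eef-1A.1 and the chaperone genes of the closing section were chosen after their values were seen. So were the neighbouring genes named because they hold or share a summit.

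Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The tests were first run on simulated peaks in 20 runs each. With 19 of 193 summits planted in 3' UTRs the class was called in 20 of 20 runs, and 1 run with nothing planted called a class. With 19 summits planted at snoRNA starts the list was called in 20 of 20 runs, and 0 lists were called with nothing planted. With 38 shared peaks planted the mean found was 38.5, and a 6-base sequence planted in 38 windows was called in 20 of 20 runs, with 0 called otherwise. For codon usage, sets of 20 genes with raised values were called in 20 of 20 runs and 1 of 20 random sets was called.

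Alternatives fixed before the data were examined were the ce10 list, a stricter threshold at the median signal, each replicate alone, other overlap rules, list sizes and ranking, other promoter and target windows, other backgrounds, and other windows and flanks for sequence. Added after seeing the data were promoters of protein-coding genes only, a target window of 200 bp on each side, the stricter threshold for gene lists, correlation over the permissive combined list, and GC over 50 bp on each side.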

Results

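ALY-2 is a Caenorhabditis elegans relative of the Aly/REF family of mRNA export adaptors. Its binding was profiled by chromatin immunoprecipitation and sequencing in whole L4 larvae of a transgenic line, OP217, that carries ALY-2 with a GFP-FLAG tag at its C-terminus. There was 1 group with 2 biological replicates, from animals of mixed sex, so no conditions were compared. The question was where in the genome the tagged protein is found and how far the replicates share those sites. The values are peak lists, so read depth per replicate is unknown. The permissive ce11 lists held 17453 peaks for replicate 1 and 29384 for replicate 2, and 3341 for both replicates combined. Coordinates are ce11, and signal values are the authors' own per-peak values, used here to rank and describe peaks within a list, and between lists only for correlations and rank-matched comparison.

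The ce11 list past the authors' optimal IDR threshold, called the reproducible set here, held 193 peaks. The name does not mean that each peak was strong in both replicates. The 4 strongest peaks lay upstream of C47E8.11, downstream of a gene on IV, upstream of rpl-3 and in the 3' UTR of prg-1. The highest signal, 97.5, was at chromosome V 14688373 to 14688742, 58 bp upstream of C47E8.11. The second, 91.7, lay on IV at 17281160 to 17281529, 1299 bp from the nearest start, that of the snoRNA gene F26D10.24, and outside its start window, and the third, 91.3, lay on III at 3867391 to 3867760, 278 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. The fourth, 84.1, fell in the 3' UTR of prg-1, a Piwi-family Argonaute gene, on I at 7585247 to 7585616, with D2030.12 as its nearest start. Each peak spanned 370 bp, and signal ran from 32.6 to 97.5 with a median of 37.5.

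Of the 25 strongest peaks, 17 were in promoters, 3 in coding exons, 2 in 3' UTRs, 2 in introns and 1 just downstream of a gene. A snoRNA gene had the nearest start at 5 of them: F26D10.24, ZK994.7 (signal 68.4), C51F7.4 (63.4), Y75B12B.12 (54.7) and K11C4.6 (53.8). Promoter peaks included rpl-35 (65.8), tasp-1 (64.2), kel-3 (65.5), tbc-6 (63.1), aex-5 (51.6) and cdc-48.1 (52.9), the last encoding an AAA ATPase. A promoter peak of Y82E9BR.30 (73.9) had lelo-2 as its nearest start, 522 bp upstream of the summit. The summit at rpr-1, the gene of the RNA component of RNase P, lay 12 bp downstream of its start (I, 13463782 to 13464151, signal 65.7). Further noncoding genes with the nearest start to a strong peak were ZK930.13 (76.9 and 49.4), C54D2.14 (52.0), linc-80 (51.8) and the piRNA gene 21ur-6781 (55.4). Several of these summits lay inside protein-coding genes. The 49.4 summit lay in a coding exon of top-2, and the 55.4 summit in an intron of srt-47, 1648 bp from the piRNA start. The 51.8 summit lay within fasn-1. Also within genes, summits lay in an intron of vab-10 (68.6), a coding exon of asp-1, which encodes an aspartyl protease (66.5), and a coding exon of pod-2 (49.2). The peak with C45B2.8 as its nearest start (52.3) lay in the 3' UTR of hsp-3, an endoplasmic reticulum chaperone gene.

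Peaks were sparse on the X chromosome. It held 14 of the 193 peaks, or 7.25% (exact binomial 95% interval 4.02 to 11.9), against 17.7% of the genome, a ratio of 0.411 (exact two-sided binomial test, adjusted p = 0.000253 over 6 chromosomes). Chromosomes I, II and III held 38, 40 and 38 peaks, IV held 31 and V held 32, and none of these 5 passed the test. Across the chromosomes, counts departed from length (permutation p = 0.00016). The X share was 11.9% in the strongest peaks of replicate 1 alone (exact binomial test, adjusted p = 0.112) and 10.3% in the stronger peaks of the set (adjusted p = 0.123), so the call was not kept in either.

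**Figure D1:**
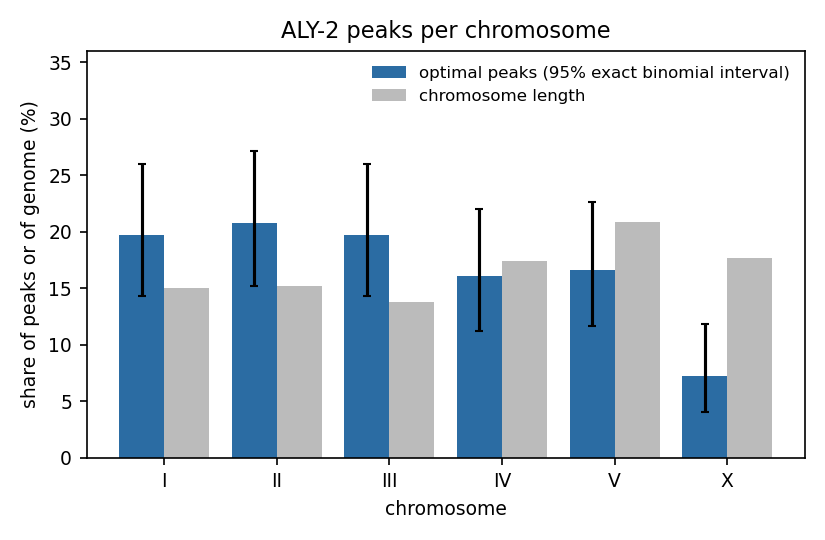
Share of the 193 reproducible peaks on each chromosome in % (blue, with exact binomial 95% intervals) beside the chromosome's share of the genome in % (grey). X holds 7.25% of the peaks and 17.7% of the genome.

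The same sites stood out in both replicates far more often than by chance, but most of each replicate's strongest peaks were not among the strongest of the other. Among the 193 strongest peaks of replicate 1, 49 overlapped 1 of the 193 strongest of replicate 2, which is 25.4% (exact 95% interval 19.4 to 32.1). Random placement within chromosomes gave a mean of 0.135% (one-sided permutation p = 0.000999, the smallest that the shuffles can give). The share was 15% with summits within 100 bp. Ranked by q it was 9.33%, but 633 peaks of replicate 2 tie at the highest value. Position in the genome picked 193 of them, so that share does not compare the strongest peaks. Sites near rpl-3 and prg-1 ranked 6 and 3 in replicate 1 and 6 and 10 in replicate 2. The coding-exon peak of asp-1 ranked 2425 in replicate 1 and 2 in replicate 2, and the peak nearest to 21ur-6781 ranked 1 in replicate 1 and 822 in replicate 2, in lists of different length.

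Every one of the 193 reproducible peaks overlapped a permissive peak of replicate 2 and 184 (95.3%) overlapped one of replicate 1, against 20.3% and 12.9% for shuffled peaks. These peaks come from the pooled alignments of the same replicates, so that overlap was largely fixed in advance. It is not independent support. Those without a replicate 1 peak included the peaks of aex-5, rps-19, F42C5.12, iff-2, F30H5.4, F54C9.12 and K07C10.2. Of the 193 peaks, 87 overlapped the 193 strongest of replicate 1, 117 those of replicate 2, 47 both and 36 neither. Across the 184 peaks found in both lists, no correlation of the replicates' signals passed the test (Pearson's r = 0.0763, permutation p = 0.301, adjusted p = 0.344; Spearman's rho = -0.0965, permutation p = 0.191, adjusted p = 0.255; 8 correlations in the family). Without the 2 peaks farthest from the median of replicate 1, r was 0.0750. Peaks are not independent replicates, and these peaks were selected on the combined signal, which by itself lowers the correlation between the replicates. Over 2407 permissive combined peaks, chosen after seeing the data, Pearson's r was 0.264 (adjusted p = 1.6e-05, permutation test) and Spearman's rho 0.00621 (adjusted p = 0.763).

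**Figure D2:**
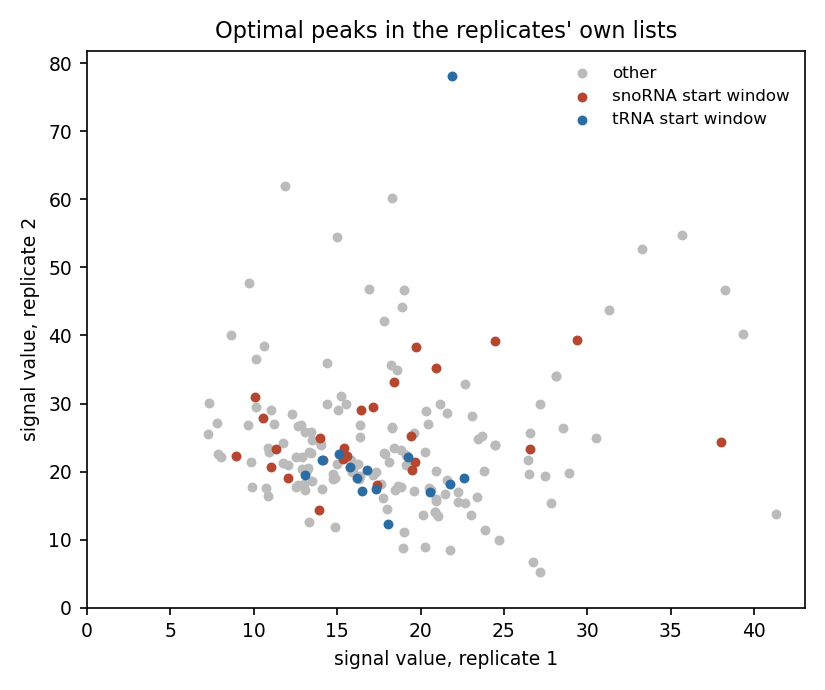
Signal value of each reproducible peak in the list of replicate 1 (x axis) and of replicate 2 (y axis), 1 point per peak found in both, in the caller's units. Peaks in the start window of a snoRNA gene are red and of a tRNA gene blue; over the 184 points Spearman's rho is -0.0965.

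Summits concentrated at gene starts and at the ends of protein-coding genes, and were rare in introns and in sequence far from genes. Promoters, taken from 1000 bp upstream to 200 bp downstream of any annotated start, held 109 summits, or 56.5% (exact 95% interval 49.2 to 63.6), against 37.8% of random placements. The 3' UTRs held 20 summits, 10.4% (6.45 to 15.6) against 2.00%, a ratio of 5.18, among them those of prg-1, hsp-3, rpl-3, alg-1 and hrde-1. Introns held 9 summits (4.66% against 25.1%), and other intergenic sequence held 2 (1.04% against 12.3%). Each of these 4 classes passed the permutation test with adjusted p = 0.0004.

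Coding exons held 39 summits (20.2% against 17.5%, permutation test, adjusted p = 0.499), the 500 bp downstream of transcript ends held 12 (6.22% against 3.32%, adjusted p = 0.0902), exons of noncoding RNA genes held 2 and 5' UTRs held 0. Among the coding-exon peaks were those of asp-1, unc-54, which encodes a myosin heavy chain, and eef-1A.1, which encodes a translation elongation factor. Against summits drawn from the permissive combined list, introns stayed past the threshold (background 12.1%, permutation test, adjusted p = 0.016), while promoters (47.7%, adjusted p = 0.0586), 3' UTRs (6.91%, 0.168) and other intergenic sequence (4.23%, 0.0559) did not. In replicate 1 alone, the promoter share was 45.6% (permutation test, adjusted p = 0.0504), and with starts of protein-coding genes only, an alternative chosen after seeing the data, promoters held 35.8% against 26.5% and introns 13.5% against 27.8%, both still past the threshold, while downstream positions rose past it with 12.4% against 3.40% (adjusted p = 0.0004).

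**Figure D3:**
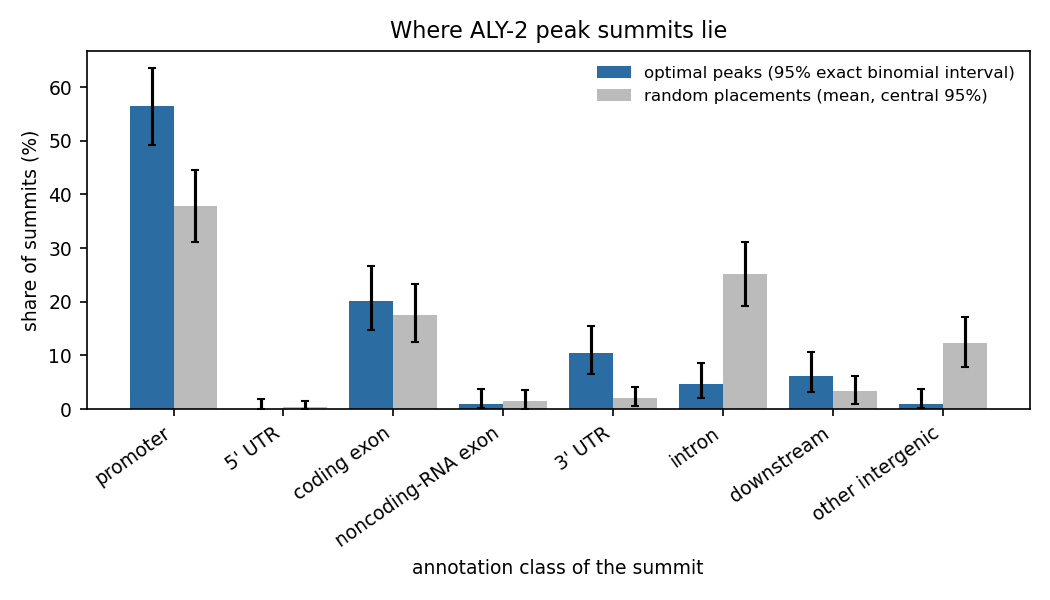
Share of the 193 summits in each annotation class in % (blue, with exact binomial 95% intervals) and the mean of random placements within chromosomes (grey, with their central 95% range). Promoters hold 56.5% against 37.8% and 3' UTRs 10.4% against 2.00%, while introns hold 4.66% against 25.1%.

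Genes for snoRNAs, tRNAs, snRNAs and ribosomal proteins carried peaks more often than other genes, while the microRNA list did not pass (2 of 262 genes, adjusted p = 0.644, Fisher's exact test) and 3 of 15363 piRNA genes had one. Of 346 snoRNA genes, whose products guide the chemical modification of other RNAs, 29 had a summit in their start window, from 28 peaks (odds ratio 27.9, Fisher's exact test, adjusted p = 1.24e-28). Of 612 tRNA genes 16 did, from 15 peaks (odds ratio 7.50, Fisher's exact test, adjusted p = 3.09e-08), and of 82 ribosomal protein genes 6 did, from 6 peaks (odds ratio 21.04, adjusted p = 6.69e-06). Among all 46890 annotated nuclear genes, 181 (0.386%) had such a summit. Adjusted values are over 24 lists.

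The snoRNA genes included ZK994.7 (signal 68.4, summit 1 bp upstream of the start), C51F7.3 and C51F7.4, which share 1 peak (63.4), F32E10.10 (48.3), Y23H5B.10 (46.2), C10C6.8 (45.7) and C41C4.11 (44.7). In the set, B0228.10, C02F5.15, C04G6.12, C05D2.15, C06A1.9, F11A10.9, F26D10.24, F30H5.4, F54C9.12, K07C10.2, K11C4.6, M106.6, T02E1.9, T04A8.17, T06C12.16, T19B4.8, W01C9.6, Y37E3.20, Y53F4B.48, Y75B12B.12, ZK265.10 and ZK546.18 were the remaining 22. The nearest of these summits to the snoRNA start lay at a median of 48.5 bp upstream, and 22 of the 28 lay within 100 bp. The tRNA summits had a median of 43 bp downstream of the start, and 13 of 15 lay within 100 bp. Among the tRNA genes, WBGene00014520 on X had signal 40.4, WBGene00006314 on III had 39.2 and WBGene00014402 on III had 38.6. In replicate 1 alone, 12 snoRNA and 9 tRNA genes were targets, and in replicate 2 alone 30 and 10, each still past the threshold.

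Ribosomal protein genes with a summit were rpl-3 (signal 91.3), rpl-35 (65.8), rpl-12 (41.8), rps-16 (33.7), rps-19 (32.9) and rpl-20 (32.7). All 6 summits lay upstream of the start, by 18 to 426 bp, and those of rps-19, rpl-20 and rpl-12 also lay in the start window of another gene (hsr-9, Y17G9B.5 and lin-54), with hsr-9 and Y17G9B.5 the nearer start. The list passed among protein-coding genes alone (odds ratio 20.3, Fisher's exact test, adjusted p = 2.22e-05). With replicate 1 alone 3 of its genes were targets (Fisher's exact test, adjusted p = 0.00999), and with a window of 200 bp on each side 2 were (adjusted p = 0.0783).

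Of 129 genes with the snRNA biotype 6 had a summit, from 5 peaks (odds ratio 12.99, Fisher's exact test, adjusted p = 7.01e-05). They were F42C5.12, C47F8.9, sup-39, mir-1831 inside it, and the spliced leader genes sls-2.2 (signal 48.95) and sls-2.4 (39.2), whose RNA is joined to the 5' end of mRNAs by trans-splicing. Both spliced leader genes also formed a call of their own, 2 of 30 (odds ratio 18.6, Fisher's exact test, adjusted p = 0.0288). All 5 summits lay 127 to 188 bp downstream of the snRNA start, and there were 0 targets with a window of 500 bp upstream and 100 bp downstream. Only F42C5.12 had the nearest start to its summit, and its peak overlapped no permissive peak of replicate 1. At the spliced leader genes other noncoding genes were nearer, C17C3.23 at sls-2.2 (-27 bp) and R12E2.18 at sls-2.4 (-47 bp, minus for upstream). At sup-39 and mir-1831 the nearest start was that of C15F1.14 (32 bp), and at C47F8.9 that of R05D7.8 (17 bp). With replicate 1 alone 2 snRNA genes were targets (Fisher's exact test, adjusted p = 0.209).

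Translation factors had 2 of 38 genes, eif-2Bgamma (signal 37.6) and iff-2 (33.9) (odds ratio 14.5, Fisher's exact test, adjusted p = 0.038). Both peaks also lay in the window of a noncoding gene, sup-39 and F54C9.12. The call did not hold among protein-coding genes (Fisher's exact test, adjusted p = 0.103), and no gene of this list was a target with replicate 1 alone.

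Of the lists that did not pass, 4 had members with a summit: his-42 of 72 histone genes (signal 33.3), cel-mir-50 and mir-1831 of 262 microRNA genes (38.7 and 37.6), cox-5B of 42 nuclear genes of the respiratory chain (34.9) and gst-27 of 62 insulin and stress response genes (37.3). None of the 41 genes of mRNA export and TREX had a summit in its window, nor did any gene of splicing (42), chaperones (60), collagens (171), hedgehog-related and molting genes (129), major sperm proteins (31), vitellogenins (6), germline granules and meiosis (49), muscle (40), intestine (290), neuronal genes (152), nuclear hormone receptors (269), homeobox factors (79) or RNA polymerase subunits (38). For these lists random placement gave under 1 summit on average, so a lack of peaks was not detectable.

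**Figure D4:**
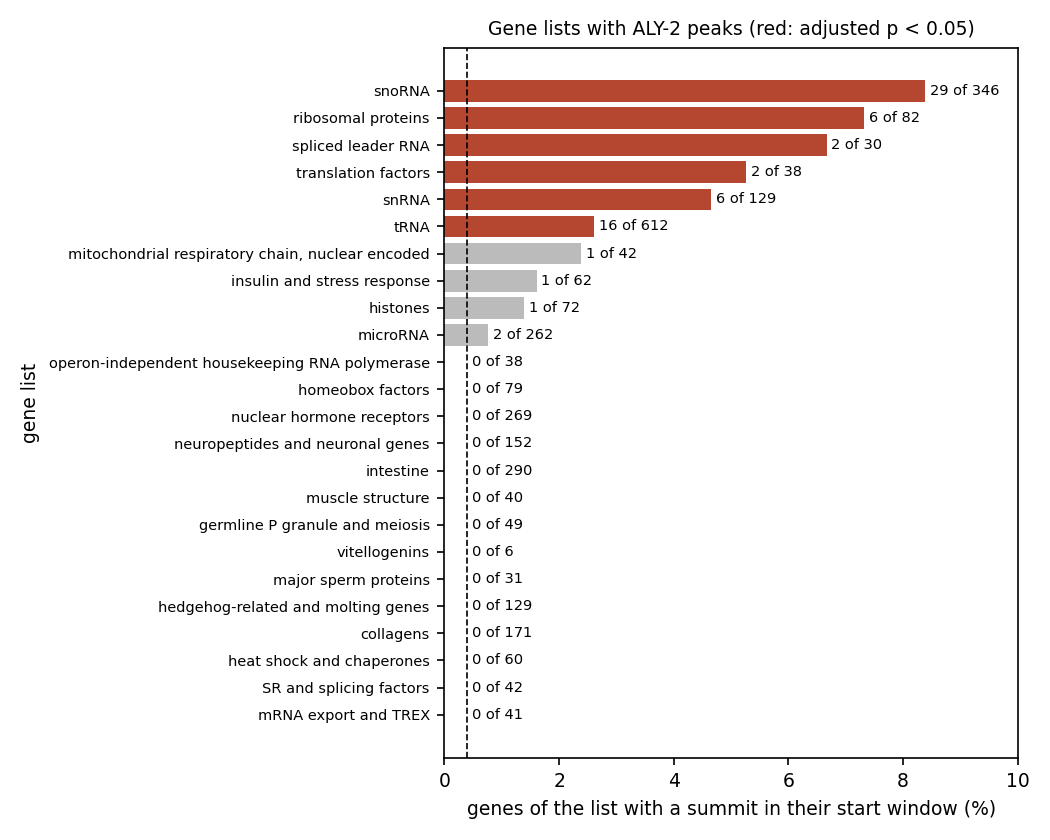
Share of each fixed gene list with a summit in the start window of its genes in %, with counts beside the bars and lists past the test in red. The dashed line is the share over all genes, 0.386%; snoRNA genes reach 8.38%.

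The sequence under the peaks was richer in G and C than the genome, and no short motif stood out. Within 100 bp of the summit, GC content was 41.7% ± 7.16 (SD, n = 193 peaks), against 35.6% for random placements (permutation p = 0.0002, the smallest two-sided value). None of 2080 sequences of 6 bases, counted with their reverse complements, differed between the summit and a flank of the same peak after adjustment (exact McNemar test), and 5.72% of them had an unadjusted p under 0.05. The leading sequences, CGCACG and CTTGCA, were in 11 and 14 windows and had adjusted p = 0.602 by the exact test. In simulation a sequence planted in 38 of the 193 windows was found. Rarer motifs, such as any confined to the snoRNA or tRNA peaks, were not simulated and may have been missed.

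The tagged gene and its relatives carried no reproducible peak. At aly-2 (IV, 9147468 to 9148579) the combined list had 1 peak within 1000 bp, with signal 17.2, above 15.2% of that list. Replicate 1 had a peak of 9.64 and replicate 2 a peak of 12.4, above 63.4% and 96.2% of their lists. No list had a peak at aly-1 (IV, 9108931 to 9109753), and aly-3 (IV, 12123282 to 12124809) had peaks in replicate 2 only, the highest 10.7. At unc-119 (III, 10902641 to 10908935), the gene mutated in this strain and named in its genotype, the highest peaks were 10.1 in replicate 1 and 5.49 in replicate 2. These are values without a test. The transgene adds extra copies of aly-2, and unc-119 is the marker of the strain. Extra copies of a locus raise its read count without binding, so peaks at aly-2 or unc-119 cannot be read as binding.

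The authors' ce10 list held 152 reproducible peaks and the ce11 list 193. Rank-matched signals of the 152 strongest differed by at most 0.399% between the builds. In both builds the reproducible list was exactly the strongest part of the combined list. The further ce11 peaks all had lower -log10 q than the highest, 2.48, which the other 152 shared. X held 13 of the ce10 peaks and 14 of the ce11 peaks.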

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

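No paired analysis was possible because there is 1 group. Depth is unknown, so what it limits cannot be given. The alternatives chosen after seeing the data were the window of 200 bp on each side, the stricter threshold for lists, protein-coding promoters only, the permissive list for correlations and GC over 50 bp. The size of the peak set with each replicate alone equals the set by construction. Replicate sharing stayed past its threshold under each of 7 alternatives, up to 25% (ce10). The lowest share by signal was 15%, with summits within 100 bp. Ranked by q it was 9.33%, but 44 and 633 peaks tie at the top, so position among ties picked the replicate 2 set. GC stayed past its threshold in each alternative run, and 0 sequences of 6 bases passed in any. The cause of the changes below was not tested, except where fewer peaks or a narrower window produce them.

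The stricter threshold left 97 peaks, 10.3% on X (exact binomial test, adjusted p = 0.123). Without each replicate in turn, X held 8.29 to 11.9%, promoters 45.6 to 53.9% and coding exons 24.4 to 25.4% (past the threshold in both). Downstream positions held 7.25% in replicate 1 alone, past the threshold (permutation test, adjusted p = 0.0179). In replicate 2 alone they held 3.11%, below the background of 3.34%. Across the same 2 settings, snRNA targets were 2 to 8 and translation factor targets 0 to 2. Against the permissive list the shares stay as they are by construction, and promoters (56.5%), 3' UTRs (10.4%) and other intergenic sequence (1.04%) lost their calls, while coding exons (20.2%) lay below that background, not above. With protein-coding promoters only, downstream held 12.4% (permutation test, adjusted p = 0.0004), promoters 35.8% and introns 13.5%. The Spearman correlation was 0.00621 over the permissive list and -0.0965 over the reproducible peaks; neither passed, while Pearson's r over the permissive list did (0.264).

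With a target window of 500 bp upstream and 100 bp downstream, snRNA and spliced leader targets were 0 and 0, translation factors 1, and 3 lists passed in place of 6. With the gene body or 1000 bp upstream, snRNA had 1 target and spliced leaders 0, since most of their summits lie past the gene's end; 5 lists passed, chaperones among them. Among protein-coding genes, where lists of noncoding genes have no test, ribosomal proteins kept the call (1 list) and translation factors (2) lost it. With 200 bp on each side ribosomal proteins had 2 and translation factors 1, and with the stricter threshold translation factors had 1. By random placement translation factors missed the threshold (permutation test, adjusted p = 0.0664).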

Other observations

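Chaperone genes had no summit in their start windows by the list test, but 5 of 60 had one in the gene body or the 1000 bp upstream (odds ratio 16.4, Fisher's exact test, adjusted p = 0.000181). They were hsp-3 (signal 52.3, 3' UTR), dnj-13 (48.1), hsp-1 (45.8), hsp-110 (42.4) and hsp-90 (34.6). All but the hsp-3 summit also lay in the start window of another gene: F54D5.7 for dnj-13, the snoRNA gene F26D10.24 for hsp-1, ufbp-1 for hsp-110 and C47E8.11 for hsp-90. This window was tested against all genes, not against protein-coding genes alone. The count comes from an alternative fixed before the data were examined, and the genes were named after it was seen. Argonaute genes, chosen after the peaks were seen, held 5 peaks: prg-1 in its 3' UTR (84.1) and a coding exon (33.1), hrde-1 in its 3' UTR (47.2) and a coding exon (44.8), and alg-1 in its 3' UTR (46.2). No test was made of this group.

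The X chromosome carries many tRNA genes, and 5 of the 16 tRNA targets lay on it, against 271 of the other 596 (31.2% and 45.5%, Fisher's exact test, p = 0.315). None of the 29 snoRNA targets did, against 33 of the other 317 (exact test, p = 0.0928). The X share of permissive peaks was 12.7% in the combined list, 16% in replicate 1 and 15.7% in replicate 2, above the 7.25% of the reproducible set (Fisher's exact test, p = 0.0243, 0.00048 and 0.000664, with the set itself part of the combined list).

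The tests below on nearest starts, on codon usage, on the next gene and on replicate sharing were chosen after the related values had been seen; those on repeated words and on the B box were set before. Peaks at snoRNA starts are the first pattern. Reads shared between copies are argued against by a median of 0% repeated words of 32 bases in the windows, 100 bp on each side, at these 28 summits, but not for tRNA summits (median 29.4%) or snRNA summits (2 of 5 over 50% repeated, against 7.41% of random positions). Of the snoRNA peaks, 89.3% lay nearer to the snoRNA start than to any protein-coding start. The mean was 74.8% for random positions in the same windows (permutation p = 0.0286). Most random positions are nearer too, so this excess argues only weakly against a neighbouring protein-coding start for the set, and not for any single peak. An open hypothesis is that these genes carry RNA polymerase III promoters, whose internal element is the B box. In the gene or the 50 bp upstream, 15 of 29 snoRNA genes with a peak held one, against 37 of 317 without (odds ratio 8.11, Fisher's exact test, p = 1.05e-06). How many of these lay inside the gene was not counted. A B box alone does not go with a peak: 586 of 596 tRNA genes without a peak held one, as did 16 of 16 with one. The design has no second condition, and strong transcription of any kind, or the tag, is not excluded.

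Peaks in 3' UTRs are the second pattern. Repeated sequence is argued against by a median of 0% repeated words at the 20 summits. High transcription of these genes may contribute. Their median codon-usage percentile, a sequence proxy for expression scored against ribosomal protein genes, was 81.7 for 20 scored genes, against 29.8 to 70.4 for random sets (permutation p = 0.0012). It was 88.5 for 31 genes with coding-exon peaks (permutation p = 0.0002), and 61.4 for 76 protein-coding genes with promoter peaks (permutation p = 0.0392, and 0.0739 with sets matched on coding length). The random sets were drawn from all scored protein-coding genes, with or without an annotated 3' UTR, and were not matched on GC content. What this adds to the difference was not tested. By the order of the classes, none of these summits, nor any random 3' UTR position, lay in the promoter window of an annotated start. Whether a next start beyond that window accounts for these peaks cannot be told apart. The median distance to another start was 1944 bp, and random positions of the same class gave 1460 to 2939 bp. The authors' lists were made with a control alignment, but its values were not used here, so this technical explanation stays open.

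The third pattern is that the replicates share few of their strongest peaks. Weak peaks near the limit may account for part of this: of the strongest 48 of these peaks in replicate 1, 41.7% were shared, against 18.8% of the weakest 48 (Fisher's exact test, p = 0.0253), and 37.5% against 10.4% in replicate 2 (p = 0.00351), but with the lists shortened to the 96 strongest of each the share was 22.9% (exact 95% interval 15 to 32.6), not above the 25.4% at 193. A snoRNA start had 28 of the strongest peaks in replicate 2 and 11 in replicate 1 (exact test, adjusted p = 0.0564 over 9 kinds), and 9 of those 11 were shared. Low sharing also held outside these kinds of site. With snoRNA, tRNA, snRNA and ribosomal protein starts left out of both replicates and the rest ranked again, 43 of 193 were shared (22.3%, exact 95% interval 16.6 to 28.8). Since 169 of the 193 strongest peaks of replicate 1 lay outside these starts already, leaving them out could change the share only a little. It therefore cannot decide whether these kinds of site contribute. The 9 kinds compared between the replicates also included promoters, coding exons, 3' UTRs, introns and downstream positions. None of the 9 passed the threshold. Sharing with those further classes left out was not tested, nor was a difference in depth between the replicates.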
